A study of Mus musculus with 3 samples.

How the data were processed

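The series holds DNase-seq of MEL cells, a murine erythroleukaemia line, treated with zinc dichloride for 24 hours (dose 125 per the labels, in a unit whose prefix is unreadable there). The labels list 3 libraries in 1 group. Of these, 2 are technical replicates of biological replicate 1, and 1 comes from biological replicate 2. No untreated library was analysed here, so the data describe treated cells and hold no test of zinc.

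The authors deposited a list of peaks and a list of hotspots (broader stretches enriched in DNase I cuts) for the whole series, and another pair for biological replicate 2. Per the deposited text records of the libraries, the alignment behind the whole-series lists is named in the records of both libraries of biological replicate 1 and is absent from that of biological replicate 2. The whole-series lists were therefore read as biological replicate 1 (2 libraries together), and the other pair as biological replicate 2 (1 library). Alignments were to mm10, per the labels. The aligner, the caller, its filters and the treatment of reads that match several places are not given in the sources used here.

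Each peak carries a score in the deposited files, a whole number no larger than the 150 bp width that every peak has. What the authors count in it is not stated, so the score was used only to rank and filter peaks within a list. Each hotspot carries the −log10 of a q value as deposited by the authors, from 1.30 up to a ceiling of 100. A further stepped hotspot score in the deposited lists was not used. The files give no read counts, so the depth of each library is unknown and no count-based interval or detection limit could be given for a single peak. With 1 list per biological replicate there is no standard deviation, and the lists are given side by side. The 95% intervals on shares of peaks or genes are Wilson intervals. They cover counting error only, and neighbouring peaks are not independent.

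Chromosome lengths were checked against the reference genome (GRCm38, the assembly called mm10) in 88 comparisons of a list with a chromosome, and all 88 lay within the reference lengths. Genes came from GENCODE mouse release 21, with 21938 protein-coding genes. Peaks on the mitochondrial genome and on other contigs were counted apart and left out of the comparisons. Positions are 1-based, in mm10.

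Sharing between lists was the share of peaks of one list that overlapped a peak of the other by at least 1 bp, set beside 100 random placements of the peaks on the same chromosomes. A promoter was the stretch within 1000 bp of any annotated transcript start of a protein-coding gene. Peak midpoints were assigned to promoter, exon, intron or intergenic sequence, in that order, and compared with the share of bases in each class. For 18 gene lists holding 264 genes, the share of genes with a promoter peak was compared with that of all other protein-coding genes (Fisher's exact test, 2-sided, Benjamini-Hochberg adjustment over the lists). The lists covered erythroid transcription factors, globins and their chaperone, haem synthesis, red cell membrane, surface and iron uptake, progenitor and leukaemia genes, metallothioneins, zinc transporters and sensor, oxidative stress, heat shock, housekeeping, megakaryocyte and platelet, myeloid, T cell, B cell, liver, neuron and glia, skeletal muscle, and pluripotency and germ line. The gene Ahsp (the globin chaperone) was not matched by symbol and was not analysed here. Genes, not samples, are the units of these tests, which describe the lists within these libraries.

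Distal peaks lay over 1000 bp from any such start. Their number within 50000 bp of a gene's start was summarised as the median over each gene list and placed among 10000 random gene lists of the same size (2-sided, adjusted over the lists). Promoters with a peak in 1 replicate alone were compared per gene list with an exact McNemar test. A comparison of the share of promoters called in biological replicate 1 and missed in biological replicate 2 (Fisher's exact test) was added after the data were examined. For 13 sequence motifs, the share of peaks with at least 1 match on either strand was divided by the share among windows of the same width placed 1000 bp from each edge of a peak and free of peaks (Fisher's exact test, adjusted over the motifs). The same ratio was given for each motif written backwards. That keeps the single-base content of the motif but not its dinucleotides, so it is a rough comparison: a CpG is lost in ETS and CREB, for example, and gained in CTCF, NF-E2, NRF1 and the metal response element.

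The comparisons, the gene lists, the motifs and the rule for naming genes were fixed before the data were examined. Genes named were a set of 33 erythroid, progenitor, zinc and stress genes, with or without a peak. From each gene list, up to 3 members with the highest peak score at the promoter in biological replicate 2 and up to 3 with no promoter peak in either replicate (in alphabetical order) were also named. So was the gene with the nearest start for each of the 10 peaks with the highest score per list. In biological replicate 1 that last part could not be applied, since 215 peaks on assembled chromosomes tied at the score of 150. Genes outside the rule are said to be so where they are named, and 1 gene that the rule names is not reported here.

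Alternatives fixed beforehand were the 50% of each list with the highest scores, autosomes alone, an overlap of at least 50% of both peaks, hotspots in place of peaks, promoter windows of 500 and 2000 bp, distances of 20000 and 100000 bp, gene comparisons within 10 classes of promoter CpG content, random lists matched on neighbouring starts, dinucleotide-shuffled sequences of 20000 peaks per list, and the same number of peaks in both lists. Comparing the peaks of one list with the hotspots of the other was added after the data were examined, as were the settings of the missed promoters (windows of 500 and 2000 bp, the same number of peaks in both lists, and 10 classes of promoter CpG content or of the highest promoter score in biological replicate 1). Promoter CpG content was counted within 1000 bp of the outermost start of each gene. Genes called at another start were therefore classed by sequence other than that under the peak.

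Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1, with pseudorandom seed 1. The tests of gene lists at promoters and at distal peaks, the overlap of lists and the searches for motifs and outlined exons were tested on simulated data. Of simulated gene lists drawn without any difference from the 21938 genes, 5.00% passed an unadjusted p of 0.05 at promoters, and 100% of lists made with 95% of their genes called were recovered. For distal peaks, a separate count was simulated for each of the same genes. There 86.7% of lists made with doubled counts were recovered, and 3.33% of unchanged lists passed. Peaks shared by neighbouring genes were not simulated, so these rates may not hold for gene lists that form clusters. The motif search found 100% of planted motifs, and the search for hotspots that outline exons found 531 of 531 planted exons among the 5784 it ran on.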

Results

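DNase-seq maps chromatin that the nuclease DNase I cuts readily, which marks active promoters, enhancers and insulators. The cells were MEL, a murine erythroleukaemia line of red cell precursors arrested before terminal maturation, after 24 hours in zinc dichloride. Zinc is known to act on transcription through the sensor Mtf1, which binds metal response elements at genes such as the metallothioneins. All 3 libraries were treated, so each comparison lies between the peak lists of biological replicates 1 and 2, or between groups of genes within a list. Biological replicate 1 (2 libraries together) had 304049 peaks and biological replicate 2 (1 library) had 106591, a ratio of 2.85. Read depth is unknown for both. Median peak scores, the authors' own values, were 62 and 30, and hotspots numbered 258249 and 82250. Of these hotspots, 55.6% in replicate 1 and 17.1% in replicate 2 sat at the ceiling of the −log10 q value.

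Sites found in biological replicate 2 were for the most part found in biological replicate 1 as well, and the reverse did not hold. Of the peaks of replicate 2, 70.6% (95% interval 70.3 to 70.8%) overlapped a peak of replicate 1, against 3.48% on average for random placements and 3.61% in the highest of 100. Of the peaks of replicate 1, 23.6% (23.4 to 23.7%) overlapped a peak of replicate 2, against 1.16% at random. In the 10% of replicate 1 peaks with the highest scores, 83.8% lay inside a hotspot of replicate 2, compared with 3.25% in the 10% with the lowest. For replicate 2 peaks inside hotspots of replicate 1, these shares were 99.99% and 85.2%. An overlap of at least 50% of both peaks lowered the shared part of replicate 2 to 50.7%.

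**Figure D1:**
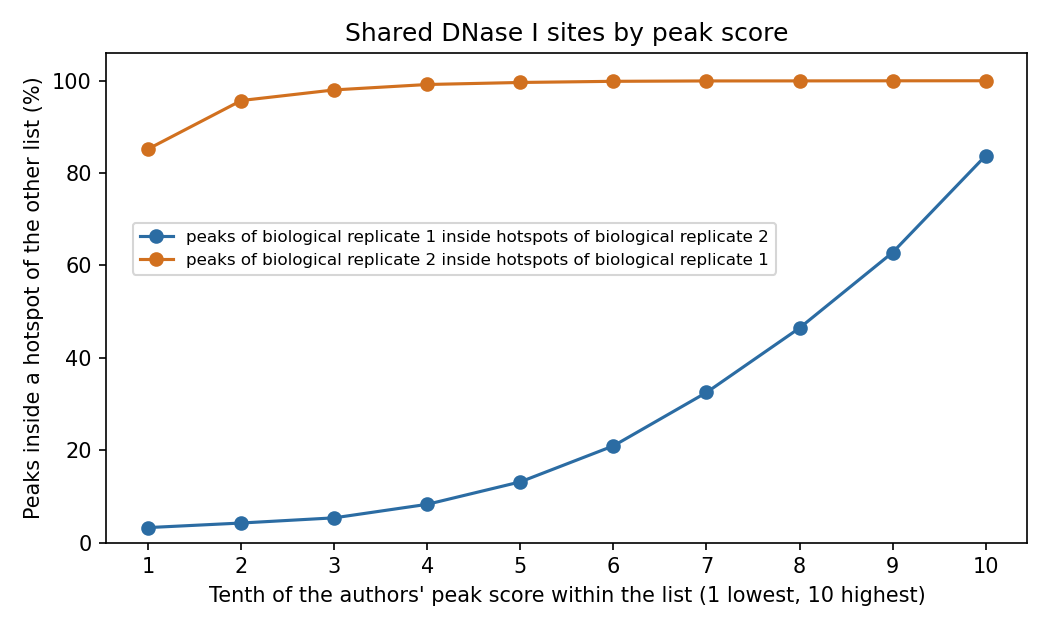
Share of peaks (%, vertical axis) that lie inside a hotspot of the other list, in 10 classes of equal size by the authors' peak score within the list (horizontal axis, 1 lowest to 10 highest). Points are the peaks of biological replicate 1 (blue), rising from 3.25% to 83.8%, and of biological replicate 2 (orange), rising from 85.2% to 99.99%.

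Promoters were overrepresented among the accessible sites of both replicates. They held 14.2% of the peaks of replicate 1 and 28.4% of those of replicate 2, 3.83 and 7.69 times their 3.70% share of the genome. Intergenic sequence held 44.5% and 37.3% of the peaks, below its 60.1% share of the genome. Introns held 37.9% and 31.3%, and exons 3.37% and 2.94%. Of 21938 protein-coding genes, 13953 (63.6%) had a promoter peak in replicate 1 and 10758 (49.0%) in replicate 2, with 10731 in both. The share of peaks at promoters moved with the window, from 9.18% at 500 bp to 20.5% at 2000 bp in replicate 1.

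The regulators of the red cell programme had accessible promoters. All 16 erythroid transcription factors had a promoter peak in replicate 1 and 14 of 16 had one in replicate 2. Gata1, the master regulator of erythroid genes, had a promoter peak of score 143 in replicate 1 (chromosome X, 7964216 to 7964365) and 57 in replicate 2 (7964036 to 7964185). Scores at Klf1, which activates adult globin genes, were 115 and 40, and those at Tal1 were 126 and 52. Each pair of scores is given as replicate 1 then replicate 2, and ranks only within its own list. Gfi1b had scores of 133 and 32, Zfpm1 (the GATA1 cofactor FOG1) 136 and 56, Lmo2 135 and 48, and Bcl11a, a repressor of embryonic globin genes, 133 and 43. The highest replicate 2 scores of the list were at Cbfa2t3 (147 and 71) and Gata1, followed by Foxo3 (145 and 56) and Zfpm1 with equal scores in replicate 2. Nfe2, which encodes a subunit of the globin activator NF-E2, scored 146 in replicate 1 and had no promoter peak in replicate 2. The list exceeded all other protein-coding genes in both replicates (Fisher's exact test, adjusted p = 0.00621 and 0.00892).

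All 22 genes of the red cell membrane, surface and iron uptake had a promoter peak in replicate 1 (adjusted p = 0.00115, Fisher's exact test) and 15 of 22 in replicate 2 (adjusted p = 0.175, and 0.0375 in an exact test within 10 classes of promoter CpG content). Among them were Icam4 (scores 136 and 71), the erythropoietin receptor gene Epor (145 and 59) and the transferrin receptor gene Tfrc (141 and 47). The anion exchanger gene Slc4a1 scored 48 in replicate 1 and had no promoter peak in replicate 2. Of 12 haem synthesis genes, 11 and 10 had a promoter peak (Fisher, adjusted p = 0.134 and 0.0520), with Alad (143 and 73), Ppox (149 and 62) and Uros (135 and 62) leading. With the highest-scoring 50% of peaks the list exceeded other genes in both replicates (Fisher, adjusted p = 0.0442 and 0.0195). Within 10 classes of promoter CpG content it did not pass in either (adjusted p = 0.276 and 0.205, exact test within classes). Alas2, the erythroid first enzyme of haem synthesis, scored 92 in replicate 1 and had none in replicate 2, and Slc25a37, the mitochondrial iron importer mitoferrin, had none in either.

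Of 10 globin genes, 5 had a promoter peak in replicate 1 (adjusted p = 0.709, Fisher's exact test) and 0 in replicate 2, where 49.1% of other genes had one (adjusted p = 0.00892). Hbb-bt, an adult beta-globin gene, scored 102 in replicate 1 (chromosome 7, 103813916 to 103814065), and its neighbour Hbb-bs scored 29. The remaining globin genes with a peak there were Hbb-bh2 (52), Hbq1a (126) and Hbq1b (82), named after their values were seen. The alpha-globin genes Hba-a1 and Hba-a2 and the embryonic Hba-x had no promoter peak in either replicate. Several globin genes are near-identical copies, and how reads matching several copies were treated is not given in the sources used here. Within 10 classes of promoter CpG content, the background for replicate 2 was 20.4% and the call ended (adjusted p = 0.205, exact test within classes). In replicate 1 the direction turned there, with 50% of globin promoters against 36.5% (adjusted p = 0.596 in the same exact test).

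No list of zinc genes passed the test against other genes at promoters in either replicate. Of the 4 metallothioneins, which bind zinc in the cytoplasm, Mt1 and Mt2 had a promoter peak in both replicates and Mt3 and Mt4 had none in either (adjusted p = 0.750 and 1.00, Fisher's exact test). A list of 4 genes is too small to pass this test even with all 4 called, so it decides nothing for metallothioneins. The Mt1 peak of replicate 1 spanned the transcript start (chromosome 8, 94178956 to 94179105, score 147), and that of replicate 2 lay just upstream (94178856 to 94179005, score 54). Mt2 scored 146 and 56. Of 25 zinc transporters and sensor genes, 21 and 18 had a promoter peak (Fisher, adjusted p = 0.111 and 0.0597). These shares of 84.0% and 72.0% lay above the 63.6% and 49.0% of other genes without passing after adjustment. The sensor Mtf1 scored 139 and 41, the zinc exporter Slc30a1 138 and 33, and the importer Slc39a10 144 and 55, while Slc30a10 scored 131 in replicate 1 alone. The leading scores of replicate 2 were at Slc39a9 (62), Slc30a5 (58) and, with equal scores, Slc39a8 and Slc39a1 (56, the latter named after its value was seen). Slc30a4, Slc30a8 and Slc39a12 had no promoter peak in either replicate.

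All 14 oxidative stress genes had a promoter peak in replicate 1 and 12 of 14 in replicate 2 (adjusted p = 0.0121 and 0.0231, Fisher's exact test). Keap1, the sensor that restrains Nfe2l2, scored 126 and 63, G6pdx 137 and 58, and Txn1 145 and 53. Gclc, the catalytic subunit of glutathione synthesis, scored 135 and 43. Its partner Gclm scored 131, and the haem oxygenase gene Hmox1 141, in replicate 1 alone. Of 14 heat shock genes, 11 and 8 had a promoter peak (Fisher, adjusted p = 0.462 and 0.636), led by Hsp90ab1 (148 and 78), Hsph1 (149 and 71) and Hspa5 (150 and 63). The inducible Hspa1a and Hspa1b, near-identical neighbours, had none in either replicate, nor had Hspb1. All 16 housekeeping genes had one in both replicates (Fisher, adjusted p = 0.00621 and 0.000200), among them Ywhaz (148 and 76), Gapdh (145 and 61) and Ppia (142 and 60). Within 10 classes of promoter CpG content the calls ended for oxidative stress in both replicates (adjusted p = 0.0775 and 0.205) and for housekeeping in replicate 1 (adjusted p = 0.0775, exact test within classes).

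Progenitor genes and genes of other blood lineages were open in part. Of 12 progenitor and leukaemia genes, 11 and 8 had a promoter peak (adjusted p = 0.134 and 0.310, Fisher's exact test). Spi1, which encodes the myeloid factor PU.1 and is activated by virus insertion in erythroleukaemia, scored 143 and 140, the latter on an exon beside an internal transcript start. Myc scored 137 and 57, Trp53 147 and 56, Myb 120 and 40, and Kit 122 and 17 at an internal start. Gata2 scored 104 in replicate 1 alone, and Hoxa9 had none in either. Of 14 megakaryocyte and platelet genes, 10 and 5 had a promoter peak (Fisher, adjusted p = 0.839 and 0.478), with Itga2b (144 and 58), Vwf (140 and 49) and Nbeal2 (143 and 46) leading and none at Gp1bb, Gp6 or Itgb3. Of 18 myeloid genes, 14 and 5 had one (Fisher, adjusted p = 0.490 and 0.175), with S100a8 (137 and 46), Cd14 (134 and 45) and Cebpe (142 and 42) leading and none at Ctsg, Elane or Ly6g. Of 16 T cell genes, 10 and 5 had one (Fisher, adjusted p = 1.00 and 0.272), with Gata3 (136 and 51), Cd3d (143 and 43) and Il7r (116 and 30) leading and none at Bcl11b, Cd2 or Cd4. Of 15 B cell genes, 9 and 4 had one (Fisher, adjusted p = 0.839 and 0.195), with Vpreb1 (142 and 49), Blnk (134 and 38) and Ebf1 (127 and 25) leading and none at Blk, Cd79a or Cr2.

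Liver genes had promoter peaks less often than other genes in both replicates, and genes of pluripotency and the germ line in replicate 2. Of 14 liver genes, 3 had a promoter peak in replicate 1 and 2 in replicate 2 (adjusted p = 0.00721 and 0.0394, Fisher's exact test). Apob scored 81 and 26, Apoa1 scored 29 in replicate 2 alone, and Cyp2e1, Cyp7a1 and Fgb had none. Of 14 pluripotency and germ line genes, 5 and 1 had a promoter peak (Fisher, adjusted p = 0.122 and 0.00892). Dazl scored 58 and 16, and Ddx4, Dppa2 and Dppa4 had none. Of 16 genes of neurons and glia, 9 and 5 had one (Fisher, adjusted p = 0.750 and 0.272), with Dlx1 (142 and 51), Tubb3 (115 and 43) and Gfap (95 and 33) leading and none at Dlx2, Gad2 or Map2. Within 10 classes of promoter CpG content this list fell below its background of 63.2% in replicate 2 (adjusted p = 0.0375, exact test within classes). Of 12 skeletal muscle genes, 5 and 3 had one (Fisher, adjusted p = 0.246 and 0.220), with Mylpf (147 and 50), Ckm (98 and 24) and Myl1 (93 and 22) leading and none at Acta1, Myf5 or Myh1. Within the same classes, the liver call ended in both replicates (adjusted p = 0.130 and 0.578), and with a 2000 bp window it ended in replicate 1 (Fisher, adjusted p = 0.116).

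**Figure D2:**
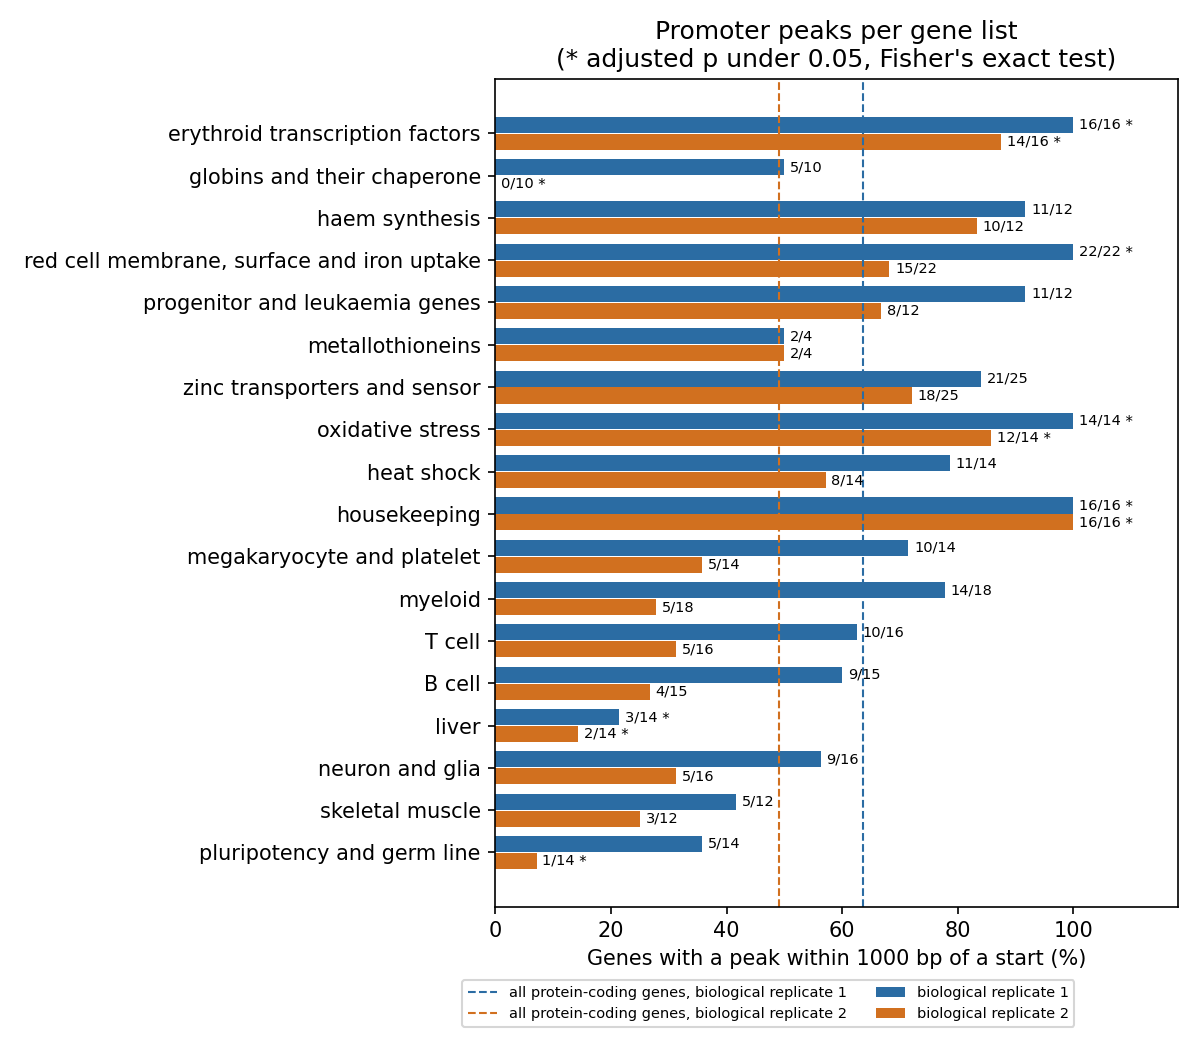
Share of genes in each of 18 gene lists with a peak within 1000 bp of a transcript start (%, horizontal axis), for biological replicates 1 (blue bars) and 2 (orange bars), with genes called out of genes in the list beside each bar and a star for an adjusted p under 0.05. Dashed lines give all protein-coding genes (63.6% and 49.0%). Erythroid transcription factors, oxidative stress and housekeeping lie above the lines in both replicates with a star, and liver below.

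Promoters called in a single replicate were nearly all called in replicate 1. Of all protein-coding genes, 3222 had a promoter peak in replicate 1 alone and 27 in replicate 2 alone. With the same number of peaks in both lists these counts were 1465 and 249. Among the gene lists, 0 of 18 passed the exact McNemar test after adjustment and 2 passed before it. That test takes both directions as equally frequent, which did not hold over all genes, so it follows the lengths of the peak lists and sets no gene list apart. In the comparison added after the data were examined, replicate 2 missed 9 of the 14 myeloid promoters called in replicate 1 (64.3%, against 23.1% of other genes) and 5 of the 5 globin promoters (adjusted p = 0.0105 for each, Fisher's exact test). Within 10 classes of promoter CpG content both calls ended, against backgrounds of 36.7% and 49.6% (adjusted p = 0.186 for each, exact test within classes). The myeloid call also ended with a 2000 bp window, at 8 of 16 promoters (Fisher, adjusted p = 0.117), and the globin call within 10 classes of the replicate 1 score (background 65.7%, adjusted p = 0.401, exact test within classes).

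In replicate 1, 7 of 18 gene lists had more distal peaks nearby than random gene lists, and in replicate 2 the myeloid list alone did. In replicate 1, the median number of distal peaks within 50000 bp was 27.5 for erythroid transcription factors, against 16 for random gene lists (adjusted p = 0.00360, where the raw p of 0.0002 is the smallest that 10000 random lists can give in a permutation test). It was 35 for metallothioneins, whose 4 genes are neighbours and share peaks, 26.5 for globins, whose 10 genes lie in a cluster on chromosome 7 and another on chromosome 11 and share peaks, 26.5 for progenitor and leukaemia genes, 25.5 for myeloid genes, 24 for housekeeping genes and 23 for red cell membrane, surface and iron uptake (adjusted p from 0.00360 to 0.0154). Random lists draw genes from across the genome. For metallothioneins and globins, and for neighbouring genes within any other list, the test therefore counts shared peaks as separate, and its p-values can be too small. Neighbours within the other lists, the myeloid list among them, were not set apart. The other 11 lists did not pass. In replicate 2, myeloid genes had a median of 10 against 3.5 (adjusted p = 0.00720 in the permutation test), and erythroid transcription factors had 8 (adjusted p = 0.0990). Within 20000 bp, 3 lists passed in replicate 1, and in replicate 2 erythroid transcription factors passed with a median of 4 against 1 (adjusted p = 0.0324 in the same permutation test). Of the 7 lists, all but erythroid transcription factors lost the call in replicate 1 under at least 1 other distance or threshold (globins within 100000 bp, adjusted p = 0.492), and the myeloid call of replicate 2 ended within 100000 bp (adjusted p = 0.144, permutation test).

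By ratio to flanking windows, sequence motifs in distal peaks were led by those of the insulator protein CTCF and of PU.1. The ratio also follows how rare a searched sequence is, so it does not rank motifs by their number of peaks. In replicate 1 the CTCF motif lay in 2.48% of distal peaks and the PU.1 motif in 2.89%, against 4.84% for AP-1 and 26.4% for plain GATA. The CTCF motif was 71.5 times as frequent in distal peaks as in flanking windows in replicate 1 (95% interval 61.2 to 83.6) and 88.7 times in replicate 2 (67.4 to 117). The PU.1 motif reached 16 (14.9 to 17.1) and 9.55 (8.26 to 11). The NF-E2 motif, bound by the erythroid factor of that name, reached 4.53 and 3.01, the RUNX motif 2.01 and 1.86, the AP-1 motif 1.956 and 1.54, and the E-box with GATA bound by Tal1 and Gata1 together 1.74 and 1.65. The plain GATA motif, short and common, was at 1.02 and 1.12, with 0.817 and 0.904 for the motif written backwards. All of these passed Fisher's exact test in both replicates, the weakest being plain GATA in replicate 1 (adjusted p = 1.37e-06). The test takes all peaks and windows as independent, which they are not, so its p-values are approximate. Plain GATA stood at 0.981 and 1.00 over all peaks and at 0.725 and 0.696 in promoter peaks, so its small distal ratio is no general enrichment.

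For the remaining distal motifs, ratios are given in the same order of replicates. The ETS motif reached 5.01 and 2.28, from 107 and 19 peaks, and NRF1 2.02 and 5.76, from 50 and 24 peaks. CREB stood at 1.75 and 1.53, little above its backward values of 1.60 and 1.47. KLF stood at 1.44 in replicate 1 and 1.01 in replicate 2 (adjusted p = 0.689, Fisher's exact test). The metal response element core stood at 1.02 and 0.969 (Fisher, adjusted p = 0.0190 and 0.0526), with 1.02 and 1.07 backwards, and the heat shock element at 0.932 and 1.07 (adjusted p = 0.131 and 0.431). The searched metal response element core is short and lay in 7.67% and 7.94% of flanking windows. Sites in a small share of peaks would hardly move such a ratio, so it does not show that they are absent. At promoters, ratios were highest for NRF1 (37.4 and 26.9), ETS (20.8 and 13.9), CTCF (18.7 and 22.6) and PU.1 (12.2 and 7.58), followed by CREB (9.07 and 6.45). The metal response element core stood at 1.71 and 1.72 in promoter peaks, below the 2.58 and 2.49 of its backward sequence, which always holds a CpG, and KLF at 2.81 and 2.09, close to 2.64 and 1.95 backwards. Over all peaks, the metal response element core stood at 1.14 and 1.20 against flanking windows and turned to 0.913 and 0.958 against shuffled sequences, while plain GATA turned from 0.981 to 1.15 in replicate 1.

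**Figure D3:**
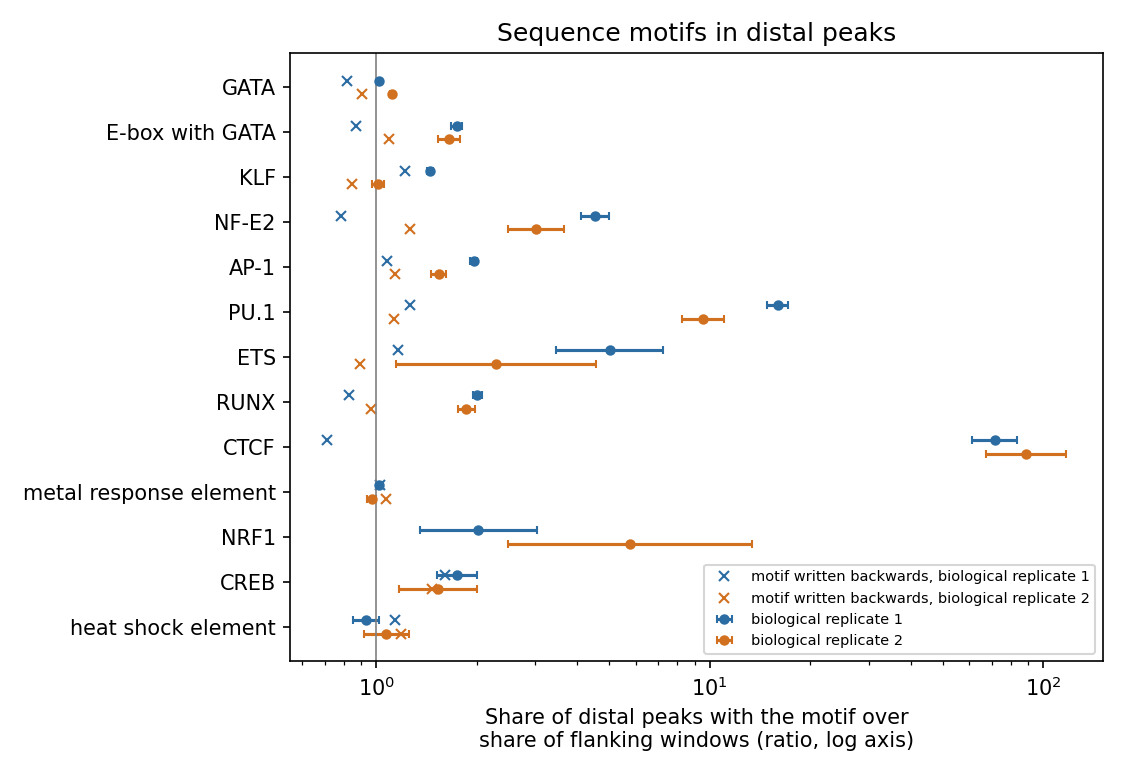
Share of distal peaks with each of 13 motifs over the share of flanking windows (ratio, logarithmic horizontal axis), for biological replicates 1 (blue) and 2 (orange). Points are ratios with bars for 95% intervals, and crosses are the same motifs written backwards. CTCF (71.5 and 88.7) and PU.1 (16 and 9.55) lie farthest to the right, and the metal response element lies at 1.02 and 0.969.

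The highest scores of biological replicate 2 lay on exons of Spi1. Of its 10 top peaks, 5 overlapped exons of Spi1 (chromosome 2, 91082390 to 91115756), with scores of 145, 145, 144, 141 and 140. The nearest gene start was that of Mybpc3 for 4 of these and of Spi1 itself for the other. Another 4 lay in intergenic sequence on chromosome 9, between 36702 and 40262 bp from the start of the chemokine receptor gene Ccr1, with scores of 139, 129, 128 and 125. The remaining peak, on chromosome 1 (183299236 to 183299385, score 124), lay in an intron of Aida, 2041 bp from the start of Brox. In replicate 1 the 3 inner exons of Spi1 had peaks of score 111, 150 and 150. In both replicates each of these exons lay under a single hotspot at the ceiling of the −log10 q value, whose ends fell between 95 and 105 bp outside the exon.

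**Figure D4:**
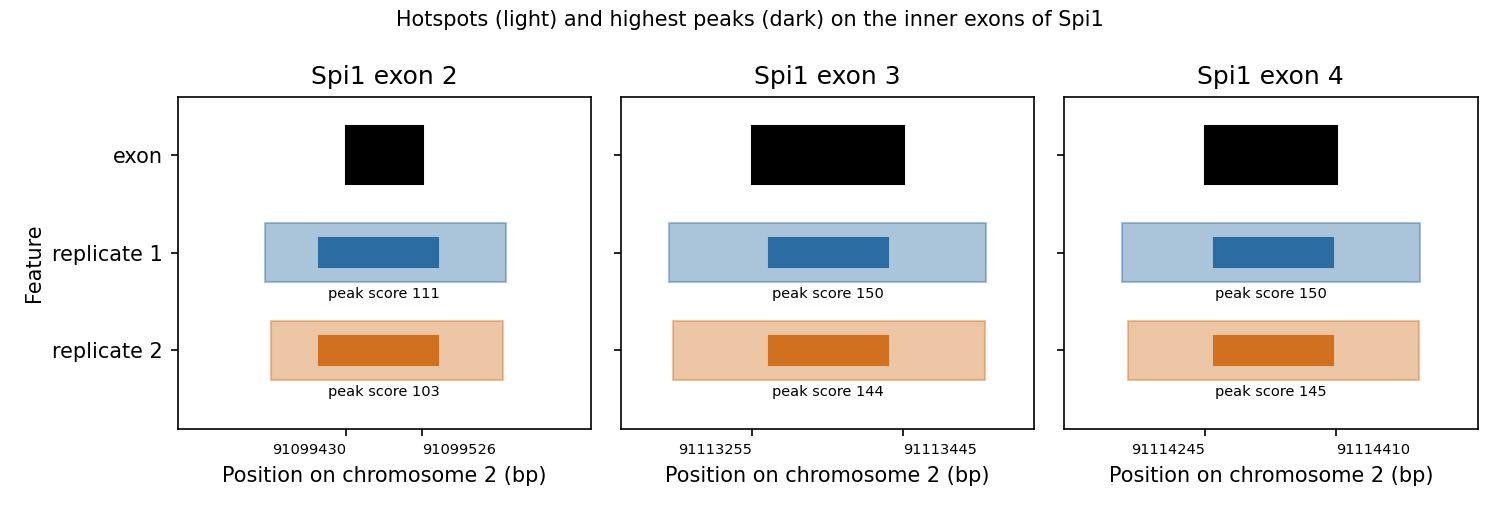
Inner exons 2, 3 and 4 of Spi1 (black) on chromosome 2 (position in bp, horizontal axis), with the hotspot (light) and the highest peak (dark, with the authors' score) of biological replicates 1 (blue) and 2 (orange). Each hotspot extends 95 to 105 bp beyond the exon on both sides.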

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

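The tests on Spi1, on the length of the lists and on independent loss of sites were chosen after the result was seen, while those on GC content and local background were written before the results they measure (the GC content of these peaks had been seen). The labels name 1 treated group, so no biological explanation was tested for any of the patterns.

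Sites outside the assembled chromosomes entered none of the comparisons. The mitochondrial genome, which carries no nucleosomes, held 17 peaks in biological replicate 1 and 30 in biological replicate 2, with median scores of 150 and 126. Other contigs held 435 peaks on 30 contigs in replicate 1 and 282 on 19 contigs in replicate 2.

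The strongest peaks of biological replicate 2 lie on exons of Spi1, the gene of PU.1, and hotspots outline its inner exons. More copies of the whole Spi1 locus, as in a duplication, would raise the introns too, and the highest score off the exons within 20000 bp was 45 in replicate 2, below the lowest best score on an exon of 103. A construct that also carries the mouse Mt1 promoter in as many copies is argued against by the score of 54 at that promoter in replicate 2, also below 103. In replicate 1 the highest score off the exons was 143 and the Mt1 promoter scored 147. Both lay above the lowest best score on an exon of 111, so neither argument holds in replicate 1 and both rest on replicate 2. The score of 111 was that of exon 2. Exon 1 scored 141 there, and exons 3, 4 and 5 scored 150, the top of the scale, at which 215 peaks tied. Scores that reach the top of the scale separate strong sites poorly in replicate 1. Spliced Spi1 RNA or cDNA copies in the libraries stay open as a candidate explanation. In both replicates 3 of 3 inner exons were outlined, and among 255919 exons searched no other gene had 3 outlined at the ceiling. Without the ceiling, 2 genes (Spi1 included) had 3 or more in each replicate. The outer exons were not outlined on both sides. In replicate 2 the hotspot on exon 1 began inside that exon, and in replicate 1 it ran 692 bp past it. On exon 5 hotspots ran 455 and 182 bp past the exon in replicates 1 and 2. On the side facing the inner exons, hotspots ended 95 to 105 bp outside exon 1 in replicate 2 and exon 5 in both replicates. Exon 1 in replicate 1, at 692 bp, was the exception on that side. The labels name no construct.

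The list of biological replicate 1 was 2.85 times as long as that of replicate 2. Lower depth of the replicate 2 library may account for part of this, since the share of replicate 1 peaks outside replicate 2 hotspots fell from 96.7% in the 10% with the lowest scores to 16.24% in the 10% with the highest, and 2.25% of replicate 2 peaks lay outside replicate 1 hotspots. Lower contrast of accessible over other DNA cannot be told apart from depth. With the same number of peaks in both lists 1465 promoters were called in replicate 1 alone against 249 in replicate 2 alone. A shallower library could give this too, which was not tested. The share of peaks at promoters was higher in replicate 2 (7.69 times the share of the genome against 3.83), and the depths are unknown.

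Peaks among the highest-scoring 10% of replicate 1 that lie outside replicate 2 hotspots (4929 peaks) sit near each other. Loss of each site on its own, through lower depth and at the same rate for all these sites, is argued against as the whole cause. Beside such a peak, the next one 2000 to 5000 bp away lay inside a hotspot in 45.8% of 707 pairs. Beside a peak inside a hotspot it did so in 84.6% of 2167 pairs, a gap of 38.76 percentage points. The pairs were not matched on score or on class of site, such as promoter or distal. Loss of sites on their own at rates that differ between such classes therefore stays open. GC content is argued against by the same comparison, with a gap of 40.52 points among pairs of 45 to 60% GC. At 50000 to 100000 bp the shares were 86.3% and 88.0%. A local background raised by many strong peaks close together may contribute and stays open, since 21.2% of the peaks with the most neighbours within 10000 bp lay outside against 12.9% of those with the fewest, a gap of 8.32 points. Neighbours were replicate 1 peaks of any score, so strong ones were not counted apart. Among genes with a promoter peak above the 90th percentile in replicate 1, 611 of 9527 (6.41%) had no promoter hotspot in replicate 2, and the 13 of them in the gene lists were Cebpa, Csf3r, Fcgr3, Gclm, Gp1ba, Hbq1a, Hmox1, Hspa8, Hspd1, Hspe1, Itgam, Nfe2 and Slc30a10 (several named after their values were seen).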

How the results depend on the processing

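In this part, the comparison of the peaks of one list with the hotspots of the other and that of missed promoters were chosen after the data were seen. No paired analysis was possible because each biological replicate has 1 list and there is 1 group, and leaving out a replicate was not run for the same reason. Depth is unknown for both lists. Where a value changed, the cause was not tested, except where the setting itself shortens a list or widens a window.

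Keeping the 50% of peaks with the highest scores left 152024 and 53295 peaks (replicate 1, then replicate 2, here and below). The shared part of replicate 2 was 50.7% with an overlap of at least 50% of both peaks, 71.4% with the highest-scoring peaks of each list, 97.0% with hotspots in place of peaks and 97.75% with peaks in hotspots. For replicate 1 these were 17.5%, 24.4%, 23.7% and 28.1%. Peaks at promoters made up 9.18% and 20.3% with a 500 bp window, 20.5% and 35.5% with 2000 bp, and 21.3% and 40.8% among the highest-scoring peaks. Genes with a promoter peak in replicate 1 alone made up 13.1% with 500 bp, 17.7% with 2000 bp and 6.68% with the same number of peaks per list.

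Gene lists above other genes in replicate 1 numbered 2 within 10 classes of promoter CpG content and 5 with the highest-scoring peaks, against 4, and in replicate 2 they numbered 4 with 500 bp and 4 with the highest-scoring peaks, against 3. Where the number rose, the list gained was haem synthesis (Fisher, adjusted p = 0.0442 in replicate 1, 0.0427 and 0.0195 in replicate 2). Within CpG classes in replicate 2 the number stayed at 3. There red cell membrane, surface and iron uptake was gained (adjusted p = 0.0375) and oxidative stress was lost (adjusted p = 0.205, exact test within classes). Lists below other genes in replicate 1 numbered 3 with 500 bp, 0 with 2000 bp, 2 with the highest-scoring peaks and 0 within CpG classes, against 1. In replicate 2 they numbered 5 with the highest-scoring peaks and 2 within CpG classes, against 3. Lists gained below were, in replicate 1, skeletal muscle (Fisher, adjusted p = 0.0491) and pluripotency and germ line (0.00261) with 500 bp and the latter (0.0358) with the highest-scoring peaks, and in replicate 2 B cell and skeletal muscle (0.0356 each) with the highest-scoring peaks and neuron and glia (0.0375) within CpG classes. Lists with more distal peaks than random lists numbered 3 within 20000 bp, 5 within 100000 bp (heat shock gained, adjusted p = 0.0396, permutation test) and 5 with the highest-scoring peaks in replicate 1, against 7. In replicate 2 they numbered 2 within 20000 bp, 0 within 100000 bp and 2 with the highest-scoring peaks, against 1.

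The lists that changed sides of their background had not passed a test at the main setting. Within CpG classes these were, in replicate 1, globins (50% of promoters), heat shock (78.6%), T cell (62.5%) and B cell (60%), and in replicate 2 metallothioneins (50%), heat shock (57.1%) and megakaryocyte and platelet (35.7%). With 2000 bp they were metallothioneins (75%) and B cell (86.7%) in replicate 1 and metallothioneins (50%) in replicate 2. For distal peaks, a list changed sides where its place among random lists crossed their middle. The medians of these lists, in replicate 1, were those of skeletal muscle (6.5) and pluripotency and germ line (5) within 20000 bp, haem synthesis (30.5), B cell (31) and skeletal muscle (35.5) within 100000 bp, haem synthesis (16) and B cell (16) against lists matched on neighbouring starts, and neuron and glia (6.5) and skeletal muscle (7.5) with the highest-scoring peaks. In replicate 2 they were those of zinc transporters and sensor (1), B cell (1), liver (1) and neuron and glia (2) within 20000 bp, metallothioneins (7.5), zinc transporters and sensor (8), T cell (8.5) and liver (7) within 100000 bp, and haem synthesis (1.5), B cell (1), liver (1) and skeletal muscle (1) with the highest-scoring peaks. The median equalled that of random lists for skeletal muscle at 7.5, for each list at 1, and for zinc transporters and sensor at 8 and T cell at 8.5.

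Among motifs over all peaks, GATA went from 0.981 and 1.00 to 1.00 and 0.954 with the highest-scoring peaks and to 1.15 and 1.07 against shuffled sequences. The metal response element went from 1.14 and 1.20 to 0.913 and 0.958 against shuffled sequences. The heat shock element went from 0.895 and 1.08 to 1.29 and 2.13 against shuffled sequences (adjusted p = 0.000697 in replicate 2, Fisher's exact test), and to 0.968 with the highest-scoring peaks in replicate 2. The NRF1 motif gave no ratio against shuffled sequences in replicate 2. All other settings of lists at promoters, of lists at distal peaks and of motifs kept their direction: 305 also kept their side of the threshold, 15 passed it and 17 no longer did. For missed promoters of globins and myeloid genes, 6 of 10 settings kept the call and 4 ended it. Other lists were not tallied there, and some turned direction. Of these, pluripotency and germ line passed with 2000 bp (Fisher, adjusted p = 0.0439) and heat shock within classes of the replicate 1 score (0.0360).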

Other observations

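The test of PU.1 sites in this part was written before its result was seen, and the choice of 1 Mb windows was made after scores had been examined.

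Whole stretches of some chromosomes scored high in biological replicate 2. Over 1560 windows of 1 Mb with at least 20 peaks, the median of the window medians was 29. The window from 96000001 to 97000000 on chromosome 3 had a median score of 58 over 279 peaks, followed by 54 on chromosome 19 (29000001 to 30000000), 51.5 and 49.5 on chromosome 12 (112000001 to 113000000 and 113000001 to 114000000) and 50.5 on chromosome 9 (21000001 to 22000000), the last holding Epor. In biological replicate 1 the windows on chromosomes 3, 19 and 9 and the first on chromosome 12 had medians at the 99.97th, 99.0th, 99.5th and 99.9th percentile of windows. The second window on chromosome 12 stood at the 22.9th percentile there, with a median of 55.5 over 210 peaks.

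Myeloid genes had more distal peaks nearby than random gene lists in both replicates, while only 5 of 18 had a promoter peak in replicate 2. In that comparison a distal peak near several genes of a list was counted for each of them. A hypothesis was that binding sites of PU.1 make up these distal peaks. Near myeloid genes, 8 of 414 distal peaks of replicate 1 (1.93%) held the PU.1 motif, against 2.89% of all other distal peaks (p = 0.303, Fisher's exact test). In replicate 2, 0 of 156 held it, which allows a share of up to 1.92%, against 1.60% elsewhere (p = 0.187, Fisher's exact test). Neither share was above that of other distal peaks. The rule written beforehand took shares no larger than elsewhere as speaking against the hypothesis, and both shares met it. That rule made no allowance for counting error, and with such an allowance the counts are too few to decide.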
